A study of Mus musculus with 4 samples.

How the data were processed

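The 4 libraries of 5' gene-expression data fall 1 to a group, named control, aPD-1 (antibody against PD-1), D+F (doxorubicin and fasudil) and D+F+P (doxorubicin, fasudil and antibody against PD-1). Per the labels' protocols, B16F10 tumours were digested, red blood cells were lysed, debris and dead cells were removed, about 10000 cells per suspension were targeted on the 10x Chromium V(D)J chemistry, and the libraries were sequenced on an Illumina HiSeq X instrument. The labels do not say how many mice went into a library. Per the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 on GRCm38 (mm10). The deposited matrices hold whole-number UMI counts per gene and barcode, per the file headers, for barcodes already called as cells, with no normalization. The annotation release and the authors' later filters on genes and cells are not stated. Each matrix lists 31053 genes, and symbols were taken from the files. The V(D)J contigs were not used here.

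Barcodes with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, and doublets called by Scrublet (as shipped with Scanpy) were removed per library. Scrublet marked 37 of 9461 barcodes (0.391%), under the 0.5% bound below which the caller was taken not to have worked, so doublets remain in the data. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components and 15 neighbours gave Leiden clusters at resolution 1 over the 4 libraries together, without integration. Clusters were named by fixed marker lists for 16 classes, a name needing at least 3 of the class's markers each detected in at least 10% of the cluster's cells. T-like and NK-like cells and myeloid cells were clustered again and named by markers of 5 sub-classes each. A cluster was left unnamed where no list fitted, or where its 10 leading genes held more markers of another class than of its own. It was also left unnamed where its median UMIs were under 1/3 of its libraries' medians and none of those genes was its own marker. Unnamed clusters are referred to by number. The unnamed T and NK sub-clusters are 1, 2 and 7, and they stay within the T-like and NK-like share but outside every sub-class. Names end in "-like" because they rest on transcripts alone.

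Shares of cells carry exact Clopper-Pearson 95% intervals. For gene levels, UMIs were summed per library and class and divided by all gene UMIs of that class, giving CPM. The ratio of 2 libraries carries the exact conditional binomial 95% interval. A class was compared where both libraries held at least 20 cells, which leaves out CD8 T-like cells of the control library. With 1 library per group no test between groups was possible, so no p-value, standard error or count of changed genes is given, and all intervals cover counting error only. A gene at 0 UMIs in 1 library is given as a bound computed at a floor of 3 UMIs. That bound takes the other library's count as it stands, so it can be larger than the exact interval allows.

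Genes named in the text, other than those said to be chosen after their values were seen, follow a rule fixed before the data were examined, as were the 27 gene lists, the markers, the 5 comparisons and 14 alternative settings. The rule took, in melanoma-like, CD8 T-like and monocyte/macrophage-like cells, the 5 genes with the highest lower bound and the 5 with the lowest upper bound of the ratio in each treated library against control, 3 each way in D+F+P against D+F and against aPD-1, 2 each way in the other classes, fixed genes of interest, and up to 4 members at each end of every list described. Candidates needed 50 UMIs in the pair. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and receptor genes, unnamed gene models and genes whose level in the class was under 25% of that of another class in the same library were left out, the last because free RNA could set them. List members are exempt from that last condition. A list was described where at least 5 members had 20 or more UMIs in the pair, by the number of members at least 1.5-fold higher or lower, the median log2 ratio and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean expression. The lists cover MHC class I and class II presentation, type I interferon and interferon gamma responses, p53 and DNA damage, proliferation, pigmentation, immunogenic death and chaperones, the unfolded protein and integrated stress response, hypoxia and glycolysis, actomyosin and SRF/YAP targets, eat-me and do-not-eat-me signals, immediate early and dissociation genes, cytotoxic effectors, exhaustion and inhibitory receptors, naive and central memory, effector memory, T cell activation, regulatory T cells, M1-associated and M2-associated macrophage genes, phagocytosis and efferocytosis, lysosome and lipid handling, chemokines, dendritic cell maturation, extracellular matrix, and abundant transcripts of other cell types as a free RNA check. The free RNA check list was the same in every class. It therefore holds pigment genes of melanoma-like cells and C1qa and Lyz2 of monocyte/macrophage-like cells. The files hold no gene under the symbols Aldoa, Cd244a, Ifi30 and Cxcl11. Trbv usage was read from gene-expression UMIs. Gene positions come from GENCODE vM21 (GRCm38).

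Other choices were made after the data had been seen: the bounds that define low-ribosomal, high-mitochondrial clusters (median ribosomal protein share under 10% and median mitochondrial share over 5%), the Cd8a and Cd3e bound of 500 CPM for Cd8a-high sub-clusters, and 4 added alternatives, one of which removes the highest 2% of Scrublet scores. The alternatives fixed in advance were a stricter filter (500 genes, 1000 UMIs, 10% mitochondrial UMIs), no filter, doublets kept, Leiden resolution 0.5 and 2, classes from each cell's own markers, other scalings, the mean of each cell's CPM, cells thinned to 1000 UMIs, other count minimums and melanoma-like cells without Mki67 or Top2a UMIs. Thinning left out cells with fewer than 1000 UMIs.

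After the ratios were seen, the cells holding the UMIs of each named gene were counted, and the report gives the share in 1 cell where that share was large. The gene-ratio step was tested on simulated data with 200 genes set to known folds. For melanoma-like cells, D+F+P against control (10975 genes), the 95% interval held the true ratio for 95.65% of genes and excluded 1 for 60 of 67 genes set to 1.5-fold, 64 of 66 set to 2-fold and 66 of 66 set to 4-fold. For CD8 T-like cells, D+F+P against D+F (6301 genes), these were 96.16%, 32 of 59, 51 of 59 and 55 of 55. For monocyte/macrophage-like cells, D+F+P against control (1007 genes), they were 95.53%, 27 of 56, 48 of 53 and 50 of 50. These figures describe sampling of molecules and hold no variation between tumours. The work used Python 3.11.15, Scanpy 1.11.5, anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.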

Results

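Tumours grown from B16F10, a mouse melanoma line, were dissociated and profiled by 5' single-cell RNA sequencing without sorting. There was 1 library for each of 4 groups: control, aPD-1 (antibody against the checkpoint receptor PD-1), D+F (doxorubicin, an anthracycline, with fasudil, an inhibitor of the kinases ROCK1 and ROCK2) and D+F+P (all 3 agents). With 1 library per group, no difference below has a replicate check: cells of 1 library are not replicates, and each comparison is between libraries, not conditions. The files held 2529, 2525, 2809 and 2739 barcodes with 34444856, 27216211, 31937128 and 22691663 UMIs in the control, aPD-1, D+F and D+F+P libraries. After filtering, 2273, 2225, 2483 and 2443 cells remained, with median UMIs of 16121, 9570, 12882 and 1866. Intervals are exact 95% intervals and cover counting error only. Gene ratios are log2 ratios of CPM, each followed by its interval, and positions are on GRCm38.

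The cell make-up of the tumours addresses whether each treatment went with more immune cells. Melanoma-like cells, which carry the pigment genes Mlana, Pmel, Tyrp1 and Dct, made up 83.55% of control cells (interval 81.96 to 85.05), 49.30% of aPD-1 cells (47.21 to 51.40), 68.63% of D+F cells (66.76 to 70.45) and 21.86% of D+F+P cells (20.23 to 23.55). T-like and NK-like cells together made up 4.49% (3.67 to 5.42), 30.43% (28.52 to 32.39), 19.05% (17.52 to 20.65) and 68.52% (66.64 to 70.36). Unnamed clusters 4 and 15, nearest to melanoma-like cells at medians of 785 and 785.5 UMIs, held 147, 132, 164 and 101 cells. T-like cluster 12, at a median of 658 UMIs, had 640 of its 797 cells in the D+F+P library. No T marker was among its 10 leading genes, but its UMI ratio of 0.3365 lay above the 1/3 bound. Its thin barcodes were thus counted as T-like, while those of clusters 4 and 15 were not counted as melanoma-like. CD8 T-like cells were 0.484% of control cells (0.242 to 0.864, 11 cells), 14.70% of aPD-1 cells (13.25 to 16.24, 327 cells), 6.56% of D+F cells (5.62 to 7.61, 163 cells) and 19.20% of D+F+P cells (17.65 to 20.82, 469 cells). Monocyte/macrophage-like cells were 1.32% (0.892 to 1.88), 6.38% (5.40 to 7.48), 2.46% (1.88 to 3.15) and 2.21% (1.67 to 2.87) of cells. The control value was 2.64% with unnamed myeloid sub-clusters counted and 2.244% with cells named by their own markers. NK-like cells were 1.89% (1.37 to 2.54), 3.87% (3.1 to 4.75), 3.06% (2.42 to 3.82) and 14.70% (13.31 to 16.16). Regulatory T-like cells, marked by Foxp3, were 0.704%, 3.69%, 1.97% and 2.74% of all cells. Of T-like and NK-like cells they were 15.69%, 12.11%, 10.36% and 4.0%, and 18.18%, 16.6%, 13.8% and 10.69% with low-ribosomal clusters left out. Neutrophil-like cells numbered 20, 12, 4 and 4 in the control, aPD-1, D+F and D+F+P libraries. Dead-cell removal and tissue digestion can change such shares, so they describe the suspensions loaded.

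A large part of the D+F+P lymphocytes were thin barcodes. Sub-clusters 2, 3 and 5 of the T and NK cells had median ribosomal protein shares of 8.47%, 7.40% and 7.96% and median UMIs of 652, 1057 and 666. These low-ribosomal barcodes were 42.86% of all D+F+P cells (40.88 to 44.85), against 0.616% (0.337 to 1.03), 8.22% (7.12 to 9.44) and 4.75% (3.95 to 5.66) of control, aPD-1 and D+F cells. The remaining T-like and NK-like cells were 3.87% (3.12 to 4.75), 22.20% (20.49 to 23.99), 14.30% (12.94 to 15.74) and 25.66% (23.94 to 27.45) of cells in the 4 libraries. Among CD8 T-like cells, those outside the low-ribosomal sub-cluster were 11.37% of aPD-1 cells (10.08 to 12.76), 5.44% of D+F cells (4.58 to 6.40) and 11.62% of D+F+P cells (10.38 to 12.96). NK-like cells outside it were 1.76%, 1.93%, 1.89% and 2.74% of cells. The shares of these remaining cells keep the low-ribosomal barcodes in the total, which lowers those of the D+F+P library most. With low-ribosomal clusters left out of the total too, T-like plus NK-like cells were 24.79%, 15.54% and 46.27% of aPD-1, D+F and D+F+P cells. CD8 T-like cells were then 12.69% of aPD-1 and 20.96% of D+F+P cells. NK-like cells were 1.816%, 2.158%, 2.058% and 4.945% in the 4 libraries. The order of the libraries in melanoma-like, T-like plus NK-like and CD8 T-like shares held in 10 of 10 settings, and that of monocyte/macrophage-like shares in 6 of 10. Some of these settings could not change a share. Counting unnamed myeloid sub-clusters alters only the monocyte/macrophage-like share, and counting every Cd8a-high sub-cluster only the CD8 T-like share. Leaving the low-ribosomal clusters out put the D+F+P melanoma-like share at 36.38% and its monocyte/macrophage-like share at 3.985%, and the stricter cell filter put them at 37.96% and 3.604%.

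**Figure D1:**
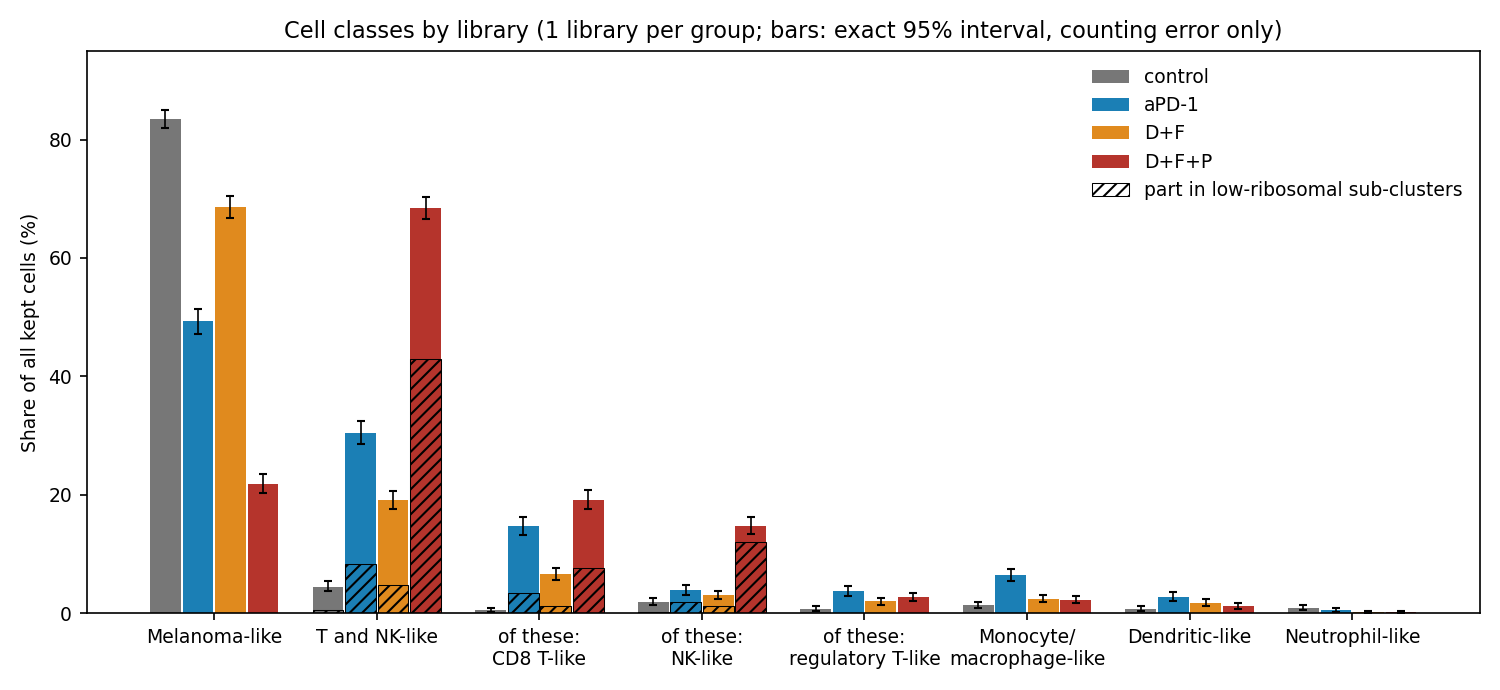
Percent of kept cells per class in each of the 4 libraries, with the low-ribosomal, high-mitochondrial part of each bar hatched and exact 95% intervals for counting error. Of all D+F+P cells, 68.52% were T-like or NK-like and 42.86% were low-ribosomal lymphocytes.

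The series names effector memory-like CD8 T cells, and 4 sub-clusters of the lymphocytes carried Cd8a above 500 CPM. Sub-clusters 3, 6 and 8 were named CD8 T-like. Sub-cluster 8 had Cd8a (6: 71373427 to 71379173) at 903 CPM and Ccl5, a chemokine of effector and memory T cells (11: 83525778 to 83530518), at 8880 CPM. It held 0.132%, 8.45%, 3.54% and 5.85% of cells in the control, aPD-1, D+F and D+F+P libraries. Sub-cluster 6, which expressed cell-cycle genes, held 0.264%, 2.92%, 1.89% and 5.77%. Sub-cluster 7, left unnamed, was led by the granzyme genes Gzmf and Gzme and held 0.044%, 3.01%, 1.29% and 2.25%. In it, 96.13% of cells had a Cd8a or Cd8b1 UMI and no Cd4 UMI, so the CD8 T-like class leaves out these granzyme-rich cells. Sub-cluster 1, also unnamed, combined Ccl5 at 9872 CPM, Ly6c2 at 1333 CPM and the granzyme gene Gzmk at 274.4 CPM with Tcf7, a transcription factor of naive and memory T cells, at 106.2 CPM. Its summed effector memory list stood at 13675 CPM, against 12385 CPM in sub-cluster 8, and Ccl5 made up most of both sums. Its summed naive and central memory list stood at 892 CPM, against 90 CPM in sub-cluster 8. That sum was 794 CPM in the regulatory T-like sub-cluster 0 and 575.5 and 1226 CPM in the NK-like sub-clusters 4 and 5. Interferon-induced genes such as Ifit3, Isg15 and Rsad2 were among its leading genes. Its summed type I interferon list stood at 5708 CPM, against 2800 CPM in sub-cluster 8 and 6552 CPM in sub-cluster 0. In sub-cluster 1, 53% of cells had a Cd8a or Cd8b1 UMI and no Cd4 UMI, against 97.39% in sub-cluster 8 and 7.61% in the NK-like sub-cluster 4, and 11.67% had a Cd4 UMI and neither Cd8 gene. Cells with none of these UMIs (34.7%) cannot be assigned at a median of 2119 UMIs. It held 0.968% of control cells (0.608 to 1.46), 2.20% of aPD-1 cells (1.63 to 2.90), 3.71% of D+F cells (3.0 to 4.53) and 6.30% of D+F+P cells (5.37 to 7.34). The thin sub-cluster 2 had Tcf7 at 113.8 CPM and held 0.396%, 2.97%, 2.46% and 23.33% of cells.

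**Figure D2:**
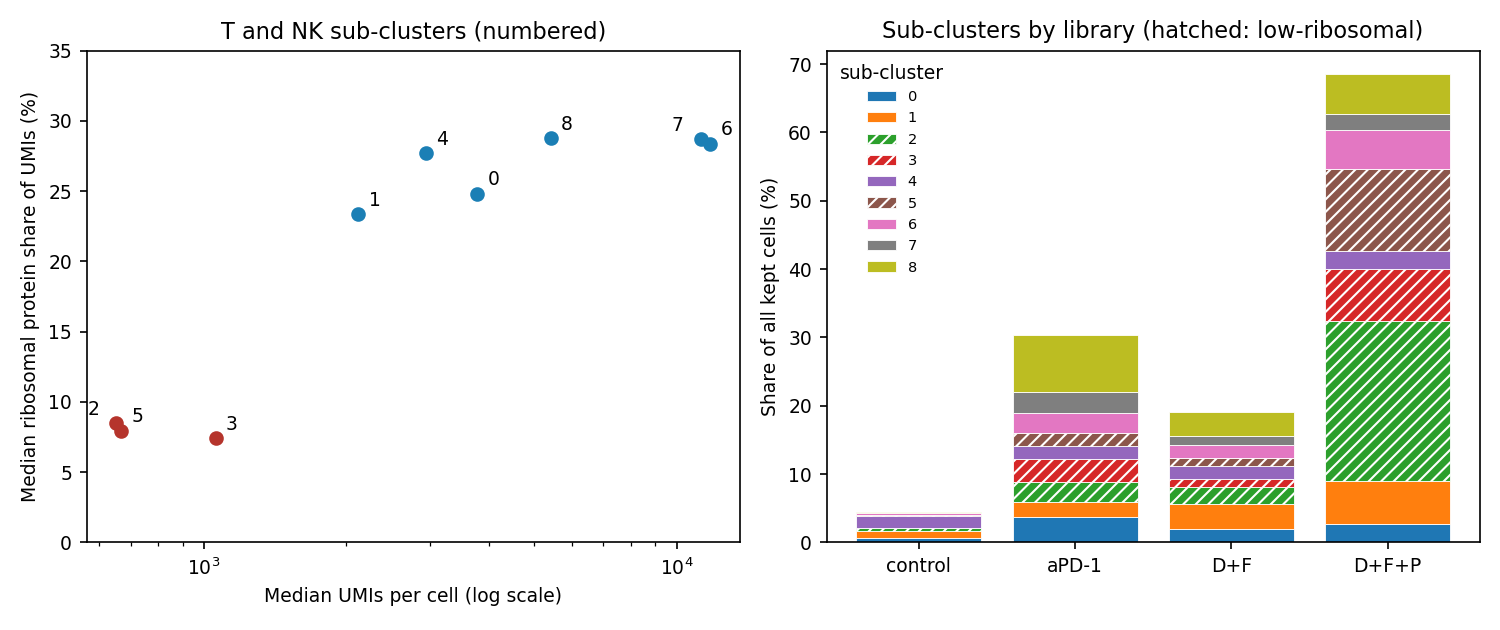
Left, median UMIs per cell (log axis) against the median ribosomal protein share for each T and NK sub-cluster. Right, the percent of each library's kept cells in each sub-cluster, with low-ribosomal sub-clusters hatched; these held 62.55% of T-like and NK-like cells in the D+F+P library and 27.03% in the aPD-1 library.

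Melanoma-like cells of all 3 treated libraries had higher levels of antigen presentation and interferon-induced genes than those of the control library. The D+F+P library had the highest medians, but for type I interferon genes its lead turned after thinning, to -0.04 against D+F and -0.02 against aPD-1. Of 17 measured interferon gamma response genes, 14, 12 and 17 were at least 1.5-fold higher in the aPD-1, D+F and D+F+P libraries than in control, with median log2 ratios of 0.92, 0.80 and 1.34, each at percentile 100 of matched random lists. MHC class II genes, which present peptides to CD4 T cells, had medians of 1.81, 1.40 and 2.58, with 9 of 10 higher in each library at percentile 100. MHC class I genes, which present peptides to CD8 T cells, had 6, 4 and 13 of 16 higher and medians of 0.50, 0.38 and 0.78. The type I interferon list had 7, 5 and 9 of 20 higher and medians of 0.38, 0.34 and 0.48. Proliferation genes were lower: 17, 9 and 17 of 20 by 1.5-fold or more, with medians of -0.76, -0.57 and -0.91 at percentile 0. Median-of-ratios scaling moves the median of all genes by 0.10 in D+F+P against control. Most control cells of this class lay in clusters 0 and 3, which held 486 and 526 of 1899 cells, and cluster 5 held 223 of the 534 D+F+P cells against 103 control cells.

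In the aPD-1 library against control, the melanoma-like genes highest above control were Kcnj13, a potassium channel gene (1: 87386363 to 87394729; 2.41, 2.14 to 2.70), the MHC class II gene H2-Eb2 (2.51, 1.86 to 3.21), Gbp10 (2.03), Rapgef5 (2.05) and Armc3 (2.18). Ciita, the master regulator of MHC class II genes, had a ratio of 1.88 (1.48 to 2.29), H2-Aa 1.92 (1.87 to 1.98), Socs1, a feedback inhibitor of cytokine signalling, 1.5 (1.25 to 1.75), and Cd274, which encodes PD-L1 (19: 29367455 to 29388095), 1.13 (0.97 to 1.30). Cxcl9, a chemokine that attracts T cells, went the other way in these cells at -1.09 (-1.34 to -0.85). The lowest were Serpina3n, a serine protease inhibitor gene (12: 104406729 to 104414329), at 0.287 against 12.93 CPM (-5.49, -6.95 to -4.36), Mro with 3 against 54 UMIs (-3.52, -5.85 to -1.90), Cbr2 (-1.92), Tslrn1 (-2.04) and Prokr1 (-2.11). Among cell-cycle genes, Cdk1 stood at -1.16 (-1.24 to -1.09), Top2a, the topoisomerase that doxorubicin poisons (11: 98992943 to 99024189), at -0.85 (-0.92 to -0.77) and Mki67 at -0.73 (-0.82 to -0.65). The hypoxia and glycolysis list was higher, with 6 of 19 members and a median of 0.28 at percentile 100, led by Ndrg1 (1.15) and Ankrd37 (1.08). The p53 target Cdkn1a stood at -0.35, and Gdf15, another, at -1.95 (-2.42 to -1.51).

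In the D+F library against control, 3 genes best known from keratinocytes had the largest ratios in melanoma-like cells, and a few cells set them. Krt5, a basal keratin gene (15: 101707070 to 101712898), had 186 UMIs against 0, at least 71.5-fold higher, the water channel gene Aqp3 had 114 against 0, at least 43.8-fold higher, and Ly6d had 94 against 1 (6.76, 4.25 to 12.08). These UMIs lay in 13, 5 and 8 of 1704 cells, and 1 cell held 59.7%, 54.4% and 61.7% of them, so the intervals for counting error do not apply to the class as a whole. Trim69 (2.81, 2.22 to 3.45) and Kcnj13 (2.13, 1.86 to 2.42) followed. The lowest were Serpina3n (-5.35, -6.49 to -4.41), Cbr2 (-1.95), the mitotic regulator Fbxo5 (-1.57, -1.77 to -1.36), Mro (-2.38) and the proline synthesis gene Pycr1 (-1.75). Of the genes that encode the drugs' known targets, Top2a was lower at -0.84 (-0.91 to -0.77), as proliferation genes were, while Rock1 (18: 10064401 to 10182045) stood at -0.14, Rock2 (12: 16894895 to 16987823) at 0.19, and the actomyosin and SRF/YAP list at a median of -0.05, percentile 67.8. The p53 and DNA damage list had a median of 0.05 (percentile 95.5) with 1 of 19 members higher, and Cdkn1a (17: 29090976 to 29100727) stood at 0.07 (0.03 to 0.12), a direction that turned to -0.03 when cells were thinned to 1000 UMIs. The immunogenic death and chaperone list, which holds Calr, the calreticulin gene (0.22), had a median of -0.07 at percentile 40.4. The unfolded protein list had a median of -0.18, with Chac1 at -0.95 (-1.22 to -0.67). Hypoxia genes had a median of 0.35 (5 of 19 higher), extracellular matrix genes a median of -0.40 at percentile 0.04, with Fn1 at -1.02 (-1.15 to -0.89), and immediate early genes a median of 0.19.

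In the D+F+P library against control, H2-Eb2 was 10.6-fold higher (3.40, 2.77 to 4.08). H2-T23, the mouse Qa-1 gene whose product binds the inhibitory receptor NKG2A, stood at 2.91 (2.74 to 3.08), Gbp10 at 2.93 (2.61 to 3.27), Kcnj13 at 2.76 (2.48 to 3.05) and Trim69 at 3.07 (2.44 to 3.74). Within the interferon gamma list, Socs1 stood at 2.59 (2.35 to 2.82), Ciita at 2.51 (2.11 to 2.92), Gbp2 (3: 142620602 to 142638008) at 2.0 (1.94 to 2.07) and Cd274 at 1.34 (1.17 to 1.52, 38.4 against 15.1 CPM). H2-Aa (17: 34282744 to 34287823) stood at 2.64 (2.59 to 2.70), and among MHC class I genes H2-K1 at 0.72 (0.68 to 0.75) and B2m (2: 122147686 to 122153083) at 0.55. Serpina3n had 0 against 423 UMIs, at least 63.6-fold lower, Mro was at least 8.12-fold lower, and Afap1l2 (1 against 66 UMIs; -4.90, -10.22 to -2.37), the small heat shock gene Hspb1 (-2.40, -2.64 to -2.17) and Cbr2 (-2.65, -3.30 to -2.06) were also low. Mki67 (7: 135689784 to 135716361) stood at -1.08 (-1.19 to -0.97), Top2a at -1.09, Cdkn1a at -0.63 (-0.70 to -0.57), and the matrix gene Fn1 at -2.23 (-2.48 to -1.99). The pigment genes Pmel (10: 128704195 to 128720238) and Mlana (19: 29697824 to 29708634) stood at 0.01 and -0.15, and their list had a median of 0.04 at percentile 86.7. The hypoxia list had a median of -0.03, the p53 list -0.15, the actomyosin list -0.09, the unfolded protein list -0.27, the immunogenic death list -0.21 and the matrix list -0.25. Immediate early genes had a median of 0.31 at percentile 99.99, with Egr1 at 2.66 (2.34 to 2.99). The eat-me and do-not-eat-me list had a median of 0.40 (percentile 99.9), the lysosome list -0.01 and the phagocytosis list 0.15. Cytotoxic genes, which melanoma cells lack, had a median of 3.83 in this library, and RNA from immune cells would give 75.2% of the median member's difference, against 0.187% for MHC class II genes. For other lymphocyte or myeloid lists in these cells, medians were 0.51 (exhaustion), 0.52 (naive and central memory), 0.43 (effector memory), 0.12 (T cell activation), 0.86 (regulatory T), 0.63 (M1-associated), 0.61 (dendritic maturation) and 0.52 (chemokines). The free RNA check stood at 0.01, but it holds pigment genes of these cells, so its median cannot show free RNA here.

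**Figure D3:**
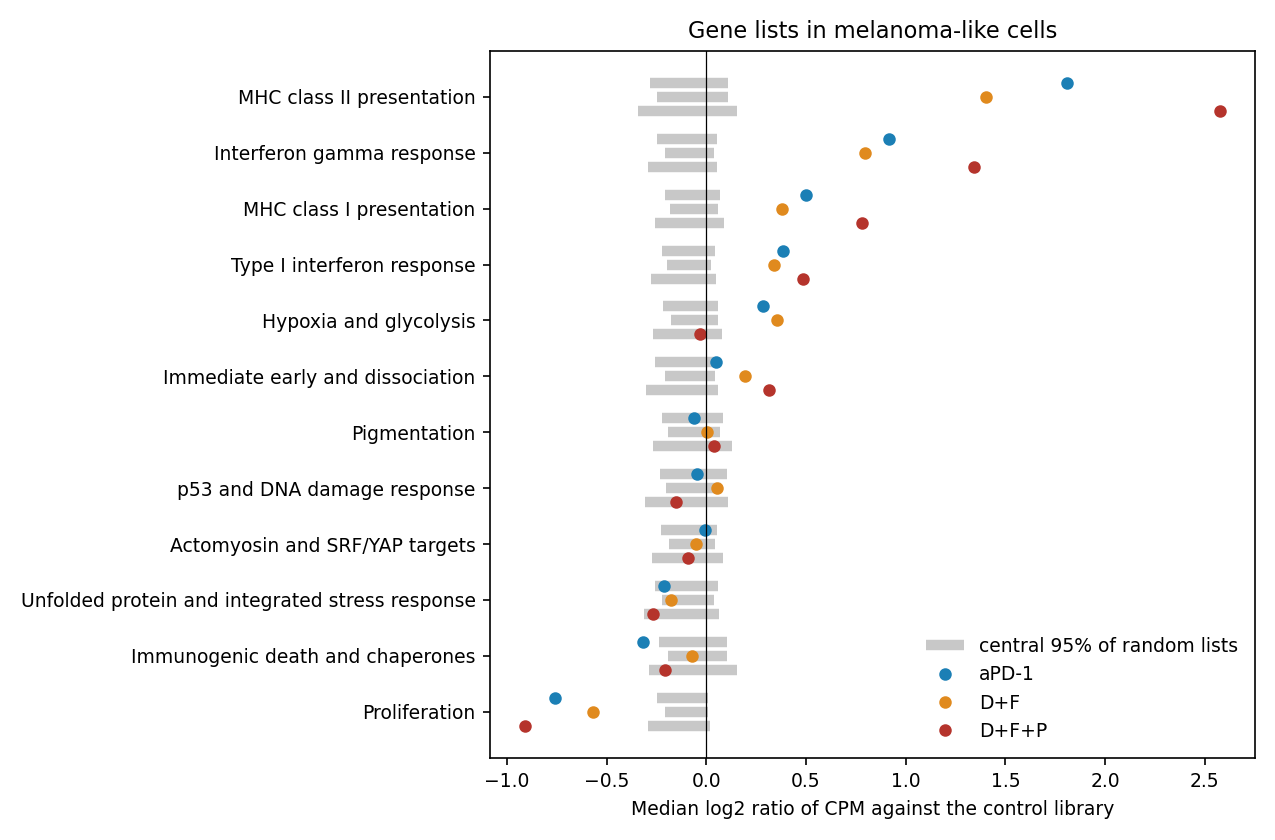
Median log2 ratio of each gene list in melanoma-like cells of the aPD-1, D+F and D+F+P libraries against control, with the central 95% of matched random lists in grey. The MHC class II medians, 1.81, 1.40 and 2.58, lie far outside the grey range, and the proliferation medians, -0.76, -0.57 and -0.91, lie below it.

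Melanoma-like cells had still higher interferon gamma response and MHC genes in the D+F+P library than in D+F. In D+F+P against D+F, 10 of 17 interferon gamma genes (median 0.67), 9 of 10 MHC class II genes (1.13) and 3 of 16 MHC class I genes (0.40) were at least 1.5-fold higher, all at percentile 100. The type I interferon median of 0.21 turned to -0.04 when cells were thinned to 1000 UMIs. Yrdc, a tRNA modification gene (2.04, 1.89 to 2.19), the ubiquitin-like modifier gene Ubd (2.38, 1.77 to 3.02) and H2-T23 (1.69, 1.56 to 1.82) led, and Socs1 stood at 1.65 (1.46 to 1.85). Krt5 had 0 against 186 UMIs, at least 32.3-fold lower, Ly6d was at least 16.3-fold lower, and Aqp3 stood at -3.89 (-5.79 to -2.49), which reflects the few D+F cells that held them. Hypoxia genes had a median of -0.31 and p53 targets a median of -0.22 (percentile 0.13), with Cdkn1a at -0.71 (-0.78 to -0.64) and Ccng1 at -0.78. Proliferation genes had a median of -0.27. Top2a stood at -0.25, which turned to 0.11 after thinning.

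In D+F+P against aPD-1, Yrdc (1.99, 1.83 to 2.16), the transcription factor subunit gene Taf10 (1.84, 1.71 to 1.98) and Sft2d3 (2.12, 1.69 to 2.57) were highest in melanoma-like cells, and Mpp2 (-1.56), the mitochondrial folate enzyme gene Aldh1l2 (-1.53) and Hist1h1t (-1.96, -3.09 to -0.97) lowest. Cxcl9 stood at 1.72 (1.46 to 1.98; 32.9% of its 422 D+F+P UMIs lay in 1 cell), Cxcl10, a related chemokine, at 0.66 (0.63 to 0.69), H2-Ab1 at 0.93 (0.87 to 0.99) and Cd274 at 0.21 (0.05 to 0.37). The list medians were 0.72 for MHC class II, 0.44 for interferon gamma, 0.23 for MHC class I and -0.28 for hypoxia. Proliferation genes had a median of -0.14 with 0 of 20 members 1.5-fold lower.

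CD8 T-like cells were compared among the treated libraries only, since the control library held 11 of them. In D+F+P against D+F, some genes of effector memory cells were higher in the class as a whole, whose make-up differed between the libraries. Gzmk (13: 113171608 to 113225908) was 2.20-fold higher at 261 against 118.6 CPM (1.14, 0.85 to 1.43), Gzma stood at 2.21 (1.63 to 2.86), Ly6c2 at 1.12 (0.93 to 1.32), the chemokine receptor gene Cxcr3 at 1.26 (0.40 to 2.26), Ccl5 at 0.72 (0.67 to 0.78), Gzmb, a main killing protease (14: 56258838 to 56262260), at 0.61 (0.53 to 0.70) and the pore gene Prf1 at 0.49 (0.30 to 0.69). Ifng (10: 118441046 to 118445892) stood at -0.16 (-0.37 to 0.05), a difference not detectable at this depth. Pdcd1, which encodes PD-1 (1: 94038305 to 94052553), stood at -0.38 (-0.51 to -0.25), Tox, a factor of exhausted T cells (4: 6686353 to 6991557), at -0.32 (-0.58 to -0.04), Cd44 at -0.65 (-1.07 to -0.22) and the granzyme gene Gzmc at -1.87 (-2.24 to -1.49). The effector memory list had 6 of 14 members higher and a median of 0.17 (percentile 96.2), inside the central 95% of matched random lists, though 0.55 after thinning, and the naive and central memory list 4 of 7 higher and a median of 1.15 (percentile 99.98), with Satb1 at 1.57 (0.68 to 2.61) and Klf2 at 1.48 (0.55 to 2.59) but Ccr7 at -2.05 (-2.57 to -1.54). Lists that stayed near 0 were cytotoxic effectors (0.04), exhaustion (-0.05), T cell activation (-0.15) and proliferation (-0.13). The hypoxia list had a median of -0.27 (percentile 0.16). Outside the lists, Rac1, a gene of actin control (5: 143503634 to 143528036), stood at 2.34 (2.0 to 2.69), the phosphatase gene Dusp2 at 2.04 (1.74 to 2.35) and Snx20 at 2.77 (1.51 to 4.42), and Ankrd37 (-2.10, -2.72 to -1.48), Ccdc184 (-1.96) and Hist1h2ak (-1.43) were lowest. Pigment genes, a sign of free melanoma RNA, had a median of -0.88 in these cells, and the free RNA check -0.88.

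In D+F+P against aPD-1, the CD8 T-like class as a whole had lower levels of exhaustion genes and of several effector genes. Exhaustion genes had a median of -0.38 at percentile 0, with Tox at -0.88 (-1.07 to -0.68), Lag3 at -0.46 (-0.60 to -0.33), Rgs16 at -0.80 (-0.86 to -0.73) and Pdcd1 at -0.31 (-0.42 to -0.21). Ifng stood at -0.57 (-0.72 to -0.41), Ccl5 at -0.32 (-0.35 to -0.29), Prf1 at -0.33 and Cd8a itself at -0.37 (-0.46 to -0.27). The cytotoxic list had a median of -0.26 at percentile 0.01. Gzmk was higher at 0.51 (0.33 to 0.69), as were Ly6c2 (0.80, 0.66 to 0.93), Cxcr3 (1.46, 0.76 to 2.23) and Gzma (1.06, 0.75 to 1.38). Gzmb stood at 0.42 (0.35 to 0.48), which turned to -0.03 when every Cd8a-high sub-cluster was counted. The effector memory list had a median of -0.06 (percentile 13.7), and the naive and central memory list 0.60 (percentile 99.5), with Klf2 at 2.04 (1.20 to 3.0). The effector memory median turned to 0.26 after thinning, a setting that moves the median of all genes by 0.11, to 0.09 as a mean of each cell's CPM and to 0.10 with every Cd8a-high sub-cluster, and it was -0.34 without low-ribosomal clusters and -0.30 under the stricter cell filter. Rac1 (2.09, 1.86 to 2.32), the heat shock gene Hspa1a (2.84, 2.11 to 3.67) and Tmem238 (2.40, 1.51 to 3.44) were highest, and Nrn1 (-1.47, -1.73 to -1.20), Ankrd37 (-1.45) and Prr5l (-1.71) lowest. The class was made up differently: sub-clusters 3, 6 and 8 gave 185, 141 and 143 of the 469 D+F+P cells, 74, 65 and 188 of the 327 aPD-1 cells and 28, 47 and 88 of the 163 D+F cells. Cd8a, Ccl5, Lag3, Rgs16 and Nrn1 are leading genes of sub-cluster 8, and Gzmk, Pdcd1 and Cd8a are leading genes of sub-cluster 6. The summed exhaustion list stood at 7162, 4156 and 5746 CPM in sub-clusters 3, 6 and 8. The lower or higher levels of these genes, Gzmk among them, cannot be told apart from this make-up, against aPD-1 or against D+F.

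**Figure D4:**
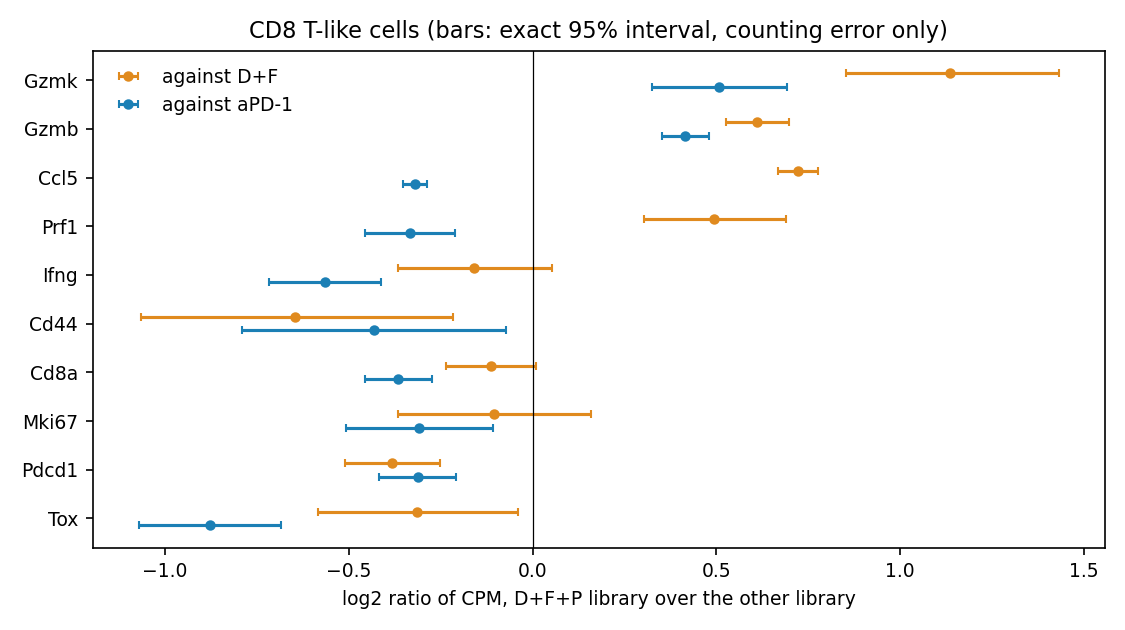
Log2 ratio of 10 genes in CD8 T-like cells of the D+F+P library against D+F and against aPD-1, with exact 95% intervals for counting error. Gzmk lies above 0 against both libraries, at 1.14 and 0.51, and Tox below 0 against both, at -0.32 and -0.88. The sub-clusters that make up the class differed in share between the libraries.

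T cell receptor beta V genes in CD8 T-like cells give a coarse view of how concentrated the cells were. Trbv12-1 (6: 41113550 to 41114067) took 29.94% of 1874 Trbv UMIs in the aPD-1 library (27.87 to 32.07) and 28.43% of 985 in the D+F library (25.63 to 31.36). In the D+F+P library Trbv13-2 (6: 41121396 to 41121832) led with 26.64% of 3589 UMIs (25.20 to 28.12), seen in 121 cells. At least 50% of the Trbv UMIs lay in 3, 2 and 4 of the 35 Trbv genes in the aPD-1, D+F and D+F+P libraries. In the unnamed sub-cluster 1, Trbv12-2 (6: 41118851 to 41119364) took 39.37% of the D+F+P UMIs (35.90 to 42.93) and 28.21% of the D+F UMIs. In the thin sub-cluster 2, Trbv12-2 took 43.36% of the D+F+P UMIs (37.53 to 49.32). Receptor genes were not kept out of the clustering, and Trbv12-2 and Trbv12-1 were leading genes of sub-clusters 1 and 8. Usage within these groups may thus partly reflect how the groups were formed. The intervals treat UMIs as independent, which those of 1 cell are not, and reads of near-identical V segments are split in an unknown way.

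In sub-cluster 1, with effector memory and naive genes together, some cytotoxic genes were higher in the D+F+P library. Its cytotoxic list had medians of 0.57 against D+F (6 of 13 members higher, percentile 100), 0.81 against aPD-1 (8 of 13, percentile 100) and 0.45 against control (6 of 13, percentile 96.9, inside the central 95% of matched random lists). Gzmb stood at -0.02 (-0.26 to 0.21) against D+F, Gzma at -0.54 (-0.94 to -0.11) against control, where 1 cell held all 58 of its UMIs, and Gzmc, chosen after its values were seen, at 16.8 CPM (7.26 to 33.1) against 166.4 CPM (71.82 to 327.8) in control. Ccl4, a chemokine of activated lymphocytes, stood at 1.56 (1.17 to 1.97), 1.59 (1.13 to 2.08) and 2.54 (1.55 to 3.76), and Gzmk at 0.83 (0.29 to 1.40), 0.66 (0.08 to 1.30) and 1.44 (0.29 to 2.91). Ccr7, a homing receptor of naive and central memory cells, stood at -2.40 (-3.17 to -1.61) against control, where 1 cell held 91.3% of its UMIs, and the chemokine Xcl1 stood at -2.26 (-2.90 to -1.59), while Cd6 had 103 against 0 UMIs, at least 3.47-fold higher. Against D+F, Pdcd1 stood at 1.73 (0.98 to 2.58). The effector memory list had medians of 0.34, 0.24 and 0.11 against D+F, aPD-1 and control. Median-of-ratios scaling moves the median of all genes by -0.11 against control here, a comparison that rests on 154 against 22 cells. Cells with a Cd8a or Cd8b1 UMI and no Cd4 UMI were 27.27%, 44.9%, 52.17% and 59.74% of the sub-cluster in the control, aPD-1, D+F and D+F+P libraries, at unmatched median UMIs of 1766.5, 2279, 1735.5 and 2688, and 0%, 2.326%, 8.511% and 14.93% of the NK-like sub-cluster 4. In sub-cluster 1 the control and D+F+P intervals, 10.73 to 50.22 and 51.54 to 67.55, did not overlap. The D+F interval, 41.5 to 62.7 at a median near that of control, overlapped both. The detected share thus differed between control and D+F+P, and the ratios against control cannot be told apart from a different make-up. Unmatched depth keeps these shares from settling it.

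Monocyte/macrophage-like cells of the treated libraries had higher interferon gamma and MHC class II genes than those of the control library. The interferon gamma list had 12 of 15, 14 of 15 and 11 of 12 members higher in the aPD-1, D+F and D+F+P libraries, with medians of 0.89, 1.22 and 1.12, and the MHC class II list medians of 0.93, 1.23 and 0.98. H2-Aa stood at 1.42 (1.17 to 1.68), 1.49 (1.23 to 1.76) and 1.51 (1.25 to 1.78), and Cxcl9 (5: 92321347 to 92328079) at 0.87 (0.35 to 1.43), 1.45 (0.92 to 2.03) and 1.5 (0.96 to 2.08). Il1b, an inflammatory cytokine (2: 129364570 to 129371139), was lower at -1.83 (-2.03 to -1.63), -1.68 (-1.93 to -1.44) and -2.70 (-3.03 to -2.38). The MHC class I medians were 0.50, 0.42 and 0.49 and the type I interferon medians 0.60, 0.58 and 0.43, the last turning to -0.06 after thinning. These values rest on 30 control, 142 aPD-1, 61 D+F and 54 D+F+P cells, and the class was made up differently: macrophage-like sub-cluster 2 held 4, 48, 23 and 8 of these cells and monocyte-like sub-cluster 7 held 15, 28, 18 and 19. Counting the unnamed myeloid sub-clusters in moves the median of all genes by 0.14, 0.13 and 0.14 and turns Cd274, at 1.09, 1.22 and 0.96, to -0.11, -0.02 and -0.12.

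In the aPD-1 library against control, the interferon-induced gene Ifit2 had 70 against 0 UMIs in these cells, at least 5.30-fold higher, Rsad2, an antiviral enzyme gene, stood at 2.79 (1.53 to 4.43), Serpina3g at 4.51 (2.0 to 9.82, 100 against 1 UMI), Ms4a7 at 2.30 (1.56 to 3.16) and Fgl2 at 2.60. The complement gene C1qa (4: 136895917 to 136898803) stood at 0.80 (0.58 to 1.03), and Car6 (-4.37), Syt4 (-3.40), Ube2c (-2.45) and Chchd10 (-2.30) were lowest with Il1b. A single control cell held 85.1% of the Car6, 88.9% of the Syt4 and 71.4% of the Chchd10 UMIs. In the D+F library, Bach1, a regulator of haem metabolism (3.27, 1.85 to 5.18), Rsad2 (3.12), the monocyte chemokine gene Ccl7 (2.19, 1.80 to 2.59), Fgl2 (2.83) and Gbp2 (2.29, 1.59 to 3.08) were highest, and Chchd10 (-2.53), Hspa1a (-2.43), Car6 (-2.55) and Cd81 (-1.78) lowest. The phagocytosis list had a median of 0.60 in the D+F library (9 of 15 higher, percentile 99.9), with C1qa at 1.10 (0.86 to 1.34) and Fcgr1 at 0.94 (0.37 to 1.54), while macrophage-like sub-cluster 2 held 23 of the 61 D+F cells against 4 of the 30 control cells. That list stood at 0.00 in the aPD-1 library and at 0.18 in the D+F+P library. Lysosome genes had medians of 0.10, 0.49 and 0.56, and chemokines 0.15, 0.74 and 0.21, in the aPD-1, D+F and D+F+P libraries.

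In the D+F+P library against control, Gbp2 (2.95, 2.26 to 3.73), Slamf8 (3.46, 1.84 to 5.78, 58 against 3 UMIs), Bach1 (3.04) and Fgl2 (2.79) were among the highest, and Cd81 (-3.73), Chchd10 (-3.50), Hspd1 (-2.81) and Nr4a1 (-2.10) lowest with Il1b. Arg1, an arginase of suppressive macrophages (10: 24915221 to 24927484), stood at 2.38 (1.17 to 3.89) with 74.5% of its 55 UMIs in 1 of the 54 cells. Nos2, the inducible nitric oxide synthase gene (11: 78920787 to 78960254), had 13 against 0 UMIs, 2.47-fold higher at the floor, with an exact interval from 0.79 in log2. Both turned when unnamed myeloid sub-clusters were counted in, to -0.45 and -1.56. M1-associated genes had a median of 0.53 and M2-associated genes 0.94, and the former turned to -0.49 in that setting. Against D+F, phagocytosis genes (median -0.61, 7 of 14 lower) and chemokines (-1.01, 9 of 15 lower) were lower in the D+F+P library, with C1qa at -1.42 (-1.63 to -1.22; sub-cluster 2 held 8 of the 54 D+F+P and 23 of the 61 D+F cells), Ccl4 at -1.56 (-1.76 to -1.37) and Egr1 at -2.86, while Ifitm1 (2.83, 1.98 to 3.80; 71.3% of UMIs in 1 cell), Rac1 (2.07, 1.52 to 2.66) and Arg1 (1.78, 0.98 to 2.66) were higher. Against aPD-1, Arg1 (2.86, 2.08 to 3.69), Rac1 (2.48, 2.03 to 2.95), Ifitm1 (2.18, 1.66 to 2.72) and Cxcl9 (0.63, 0.35 to 0.91) were higher, and C1qa (-1.13), Ifit1 (2 against 64 UMIs; -3.68, -6.75 to -1.76) and the platelet factor gene Pf4 (-2.13) lower. The type I interferon list had medians of -0.32 against D+F and -0.45 against aPD-1. The free RNA check had medians of -0.59, -0.86 and -1.35 in the aPD-1, D+F and D+F+P libraries against control, and the pigment list -1.88, -1.43 and -2.52. The check list also holds genes of these cells, such as C1qa and Lyz2, so its median is not a measure of free RNA alone.

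NK-like cells of the treated libraries had lower levels of cell-cycle genes than those of the control library, and the large ratios of the granzyme genes Gzmd and Gzmg came from a few cells. Gzmd stood at 4.54 (3.71 to 5.50), 4.87 (4.04 to 5.83) and 4.19 (3.37 to 5.15) in the aPD-1, D+F and D+F+P libraries, and Gzmg had 114 against 0 UMIs in the D+F+P library, at least 10.3-fold higher. The Gzmd UMIs lay in 4, 1 and 19 of the 86, 76 and 359 cells, and 1 cell held 93% of those of Gzmg. The cytotoxic list had medians of 0.74, 0.18 and 0.50, of which the D+F value turned to -0.57 and the D+F+P value to -0.59 as a mean of each cell's CPM. Proliferation genes had medians of -1.31, -0.85 and -0.62, with Mki67 at -2.33 (-3.09 to -1.59) in the D+F+P library, where Hist1h1b (-2.60) and Ccl1 (-2.57) were lowest, with 7 and 3 control cells holding their UMIs. These cells numbered 43, 86, 76 and 359, and scaling choices move the median of all genes by up to -0.12 here. Of the D+F+P cells, 292 lay in the low-ribosomal sub-cluster 5 and 67 in sub-cluster 4, against 3 and 40 in the control, 43 and 43 in the aPD-1 and 29 and 47 in the D+F library, so the class was made up differently in each comparison.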

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

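Of the tests in this part, those of sequencing depth, of free RNA of mean makeup and of the handling response were chosen only after the results they bear on were seen.

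Low-ribosomal T-like and NK-like barcodes with much mitochondrial RNA made up 42.86% of D+F+P cells, far more than in the other libraries. Shallower sequencing is argued against by melanoma-like cells, whose median UMIs were 28555 in the D+F+P library and 17732 in control, a ratio of 1.61. For free RNA of the library's mean makeup, Mlana stood at 202.2 CPM in these barcodes and 1387 CPM in all UMIs of the library, a ratio of 0.146 (0.126 to 0.168). Barcodes rich in Mlana would hardly have been named T-like or NK-like, so this ratio cannot decide on that explanation. Cells that lost cytoplasmic RNA and kept their nuclei are a candidate explanation, since the nuclear transcripts Neat1 and Kcnq1ot1 were 13.2, 11.3 and 22.1 times as abundant per UMI as in other T-like and NK-like cells of the aPD-1, D+F and D+F+P libraries. Free RNA from lymphocytes alone was not tested. Whether treatment, digestion or dead-cell removal left such cells in the D+F+P suspension cannot be known from 1 library per group.

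Interferon gamma response genes had higher levels in melanoma-like cells of the aPD-1, D+F and D+F+P libraries than of the control library. RNA of immune cells would give at most 0.214% of the median member's difference, and without cells that had Mki67 or Top2a UMIs at least 107% of each list median was kept, which argues against immune RNA and fewer cycling cells. Treatment, which the design names, stays open, as do differences between the single tumours or suspensions, and no biological explanation was tested.

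At least 1.5-fold higher in the D+F+P than in the D+F library, in melanoma-like, CD8 T-like and monocyte/macrophage-like cells alike, were 15 genes, named after their values were seen, among them Arf6, Chmp4b, Fam49b, Gbp2, H2-T23, Jund, Lamp1, Ly6c2, Pnrc1, Rac1, Srsf2, Ybx1, Ythdc1 and Zfand5. GC content at the 5' end of transcripts is argued against by a Spearman correlation across genes of 0.04 in melanoma-like and 0.01 in CD8 T-like cells. Of the measured immediate early and dissociation genes, 17.6% were 1.5-fold higher in melanoma-like and 11.8% in CD8 T-like cells, below a bound set after the values were seen. The share among all genes was not computed, and Jund, among the 15 genes, is itself on that list. These values therefore do not decide on a handling response. Treatment and other differences between the libraries, such as their preparation, stay open.

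Some differences went opposite ways between comparisons in the main setting, and none of these contrasts was tested. The NK-like share of immune cells differed by -10.9 points between the aPD-1 and control libraries and by 7.63 points between the D+F+P and D+F libraries, or by -14.2 and -0.489 points with low-ribosomal clusters left out, so the contrast rests on those barcodes. In melanoma-like cells the hypoxia list had a median of 0.28 in aPD-1 against control and -0.31 in D+F+P against D+F. In monocyte/macrophage-like cells the type I interferon list had medians of 0.60 and -0.32 in the same comparisons. In barcodes outside the cell filter, which only the setting with no cell filter uses, T cell receptor complex genes stood at 103.4 CPM (80.93 to 130.2) in the aPD-1, 48.32 (33.66 to 67.21) in the D+F and 351.1 (307.3 to 399.4) in the D+F+P library, above 11.34 CPM (4.163 to 24.69) in control.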

How the results depend on the processing

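Of the alternatives, the removal of the highest Scrublet scores, the omission of low-ribosomal clusters, the counting of unnamed myeloid sub-clusters and the counting of all Cd8a-high sub-clusters were chosen after the data were seen, and the others before. No paired analysis was possible because each group had 1 library. Of 1924 gene ratios under an alternative, 1537 stayed within the interval of the reported value, 371 moved beyond it and 16 reversed. Of 1640 list medians, 1497 stayed, 130 moved and 13 reversed. Not every change of sign was counted as a reversal. The effector memory median of CD8 T-like cells in D+F+P against aPD-1 changed sign after thinning, to 0.26, and was counted as moved. Of 328 shares 250 stayed and 78 moved, and a share has no sign that could reverse. Counts limit the small classes most, above all the 30 control monocyte/macrophage-like cells, and for the changes below the cause was not tested unless the setting itself changes which cells are counted.

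Settings that change which cells are counted moved the shares. T-like plus NK-like cells were 71.26% of D+F+P cells at Leiden resolution 0.5 and 3.344%, 28.49%, 15.51% and 63.04% of control, aPD-1, D+F and D+F+P cells at 2. With cells named by their own markers, melanoma-like shares were 90.15%, 57.48%, 77.85% and 31.76%, T-like plus NK-like 3.652%, 25.89%, 14.62% and 48.3%, and monocyte/macrophage-like 2.244%, 8.629%, 3.464% and 3.725%, with CD8 T-like cells at 17.35%, 9.344% and 25.13% in the treated libraries. Under the stricter cell filter, melanoma-like shares were 90.26%, 56.23%, 76.68% and 37.96%, T-like plus NK-like 26.66%, 15.92% and 51.61% in the treated libraries, and in the D+F+P library CD8 T-like 25.31% and monocyte/macrophage-like 3.604%. With no cell filter, melanoma-like shares were 79.75%, 46.97% and 65.22% in the control, aPD-1 and D+F libraries. With doublets kept, T-like plus NK-like cells were 3.412%, 15.78% and 63.89% of control, D+F and D+F+P cells and monocyte/macrophage-like cells 7.589% of aPD-1 cells. Without low-ribosomal clusters, melanoma-like shares were 52.58%, 71.06% and 36.38%, T-like plus NK-like 24.79%, 15.54% and 46.27% in the treated libraries, CD8 T-like 12.69% and 20.96% in aPD-1 and D+F+P, and monocyte/macrophage-like 3.985% in D+F+P. With all Cd8a-high sub-clusters, CD8 T-like shares were 17.71%, 7.853% and 21.45% in the treated libraries. With unnamed myeloid sub-clusters, monocyte/macrophage-like shares were 2.64% and 8.449% in control and aPD-1.

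Settings that change which cells are counted also moved ratios. In CD8 T-like cells of D+F+P against aPD-1, the effector memory median was -0.34 without low-ribosomal clusters, -0.30 under the stricter filter and 0.10 with all Cd8a-high sub-clusters, where Gzmb stood at -0.03. With unnamed myeloid sub-clusters, the monocyte/macrophage-like ratios against control were -0.11, -0.02 and -0.12 for Cd274 in aPD-1, D+F and D+F+P, -0.02 and -0.49 for the M1-associated list in D+F and D+F+P, and 0.21, -0.45 and -1.56 for C1qa, Arg1 and Nos2 in D+F+P. Without cells that had Mki67 or Top2a UMIs, melanoma-like values against control were -0.08 for immediate early genes in aPD-1, -0.02 for Cdkn1a in D+F, and 0.95 and 1.60 for the interferon gamma list in D+F and D+F+P, which stood at 0.59 in D+F+P against aPD-1.

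Settings that change how counts are summed moved other values, and thinning also left out cells under 1000 UMIs. It kept 391 of the 469 D+F+P and 286 of the 327 aPD-1 CD8 T-like cells, and 99 of the 359 D+F+P NK-like cells. Its values thus mix depth with a change of cells. Thinned to 1000 UMIs, melanoma-like values against control were -0.02 and -0.22 for Cd47 in aPD-1 and D+F, -0.03 for Cdkn1a in D+F and 1.58 for the interferon gamma list in D+F+P. For D+F+P against D+F they were 0.11 for Top2a, 0.21 for Rock2 and -0.04 for the type I interferon list, and against aPD-1 0.34 for Top2a, 0.21 for Cdkn1a, -0.02 for type I interferon, 0.68 for interferon gamma and 0.03 for actomyosin genes. The effector memory median of CD8 T-like cells was 0.55 against D+F and 0.26 against aPD-1, and against control the monocyte/macrophage-like interferon gamma median was 1.72 in D+F, the type I median -0.06 in D+F+P and the NK-like cytotoxic median -0.18 in D+F. As a mean of each cell's CPM, D+F+P melanoma-like cells had an interferon gamma median of 1.53 against control and Mdm2 at 0.03 against D+F, and CD8 T-like cells had effector memory and T cell activation medians of 0.09 and 0.16 against aPD-1. Against control, the pigment median was 0.28 in D+F monocyte/macrophage-like cells and the NK-like cytotoxic medians -0.57 and -0.59 in D+F and D+F+P. With no count minimum and 0.5 UMIs added, the free RNA check in melanoma-like cells of D+F+P against aPD-1 was -0.21.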

Other observations

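No test was added for this part, and its genes and cells were chosen after their values were seen. Regulatory T-like cells numbered 49, 67 and 82 in the D+F, D+F+P and aPD-1 libraries, of which 22.45%, 14.93% and 20.73% had a Cd8a or Cd8b1 UMI and no Cd4 UMI. In the NK-like sub-cluster 4 that share was 8.511%, 14.93% and 2.326%. Over all libraries it was 18.69% (13.7 to 24.57) in the regulatory T-like cells and 7.614% (4.324 to 12.25) in sub-cluster 4. In the aPD-1 library, at similar medians of 3266 and 3278 UMIs, the intervals were 12.57 to 31.11 and 0.0589 to 12.29. Cells with Cd8 transcripts beyond that background were thus in the class, though not detectably in the D+F+P library. The ratios below describe this mixed class. In D+F+P against D+F and aPD-1, the regulatory T list of the regulatory T-like cells had medians of -0.05 and 0.06, with 2 and 3 of 13 members 1.5-fold higher and 0 lower, and chemokines had medians of 1.80 and 1.10, both at percentile 100. Ccl5 stood at 1.42 (1.18 to 1.67) against D+F and 0.87 (0.69 to 1.05) against aPD-1. Il10, which encodes an immunosuppressive cytokine, stood at 2.72 (1.26 to 4.66; 41 against 4 UMIs) and Ifng at -1.31 (-1.92 to -0.72) against D+F. Mki67 stood at -0.83 (-1.38 to -0.30) against aPD-1, where the proliferation list had a median of -0.59.

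Dendritic-like cells numbered 17, 61, 43 and 28 in the control, aPD-1, D+F and D+F+P libraries. The maturation list had a median of -1.98 in D+F+P against D+F, with 10 of 12 members lower, among them Fscn1 at -3.18 (-3.75 to -2.65) and Ccr7, which guides dendritic cells to lymph nodes, at -1.97 (-2.39 to -1.57). The activated and migratory sub-cluster held 14 of the 43 D+F cells and 4 of the 28 D+F+P cells. In the fibroblast-like cells, 25 in the D+F+P and 44 in the aPD-1 library, D+F+P levels were higher for the interferon gamma list (median 1.06), MHC class I (0.75) and p53 targets (0.73), with Gbp4 at 2.94 (2.16 to 3.80) and Mdm2 at 1.74 (1.10 to 2.40), and lower for proliferation (-1.50, 19 of 20 members lower). Their median ribosomal protein share was 19.05% against 24.73%, mitochondrial share 1.983% against 1.21% and Malat1 share 0.2984% against 0.09255%, so RNA quality differed too. In the unnamed granzyme-rich sub-cluster 7, of 55 D+F+P, 32 D+F and 67 aPD-1 cells, Ccl4 stood at 1.92 (1.66 to 2.18) against D+F and 0.90 (0.75 to 1.04) against aPD-1.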
